A study of Mus musculus with 6 samples.

How the data were processed

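The data are RNA-seq profiles of sorted mesenchymal progenitors from mouse hindlimb muscle, 3 libraries from WT and 3 from Hic1 cKO animals, grouped by the genotype in the sample titles. The series text speaks of more replicates per group than were analysed here. Per the labels' protocols, libraries were made from poly(A) RNA with a strand-specific kit. Per the submitters' processing notes, the tools used were bcl2fastq, TopHat2, Bowtie2 and Cufflinks, on mm10 (GRCm38); their versions, roles and settings, the annotation and the strand setting are not given in the sources used here. The authors deposited 1 table of FPKM per gene and library, per the file headers. Of its 24340 genes, 9 have no numeric value in at least 1 library and were left out: Cbfa2t2, Cep250, Etv3, Flii, Gsn, Kirrel, Llgl1, Mbnl1 and Usp19. The lowest value in the table is 0.01 FPKM, which stands where other pipelines write 0. FPKM is already scaled to depth and transcript length and carries no counts, so a count test was not run.

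Depth was estimated from the deposited FPKM. In genes with 1 annotated transcript of at least 1500 nt and values under 0.5 FPKM, the product of FPKM and transcript length less 150 nt rises in steps of single fragments. The step gave 17900000 to 27820000 fragments per library, with a median of 20890000 in WT and 26320000 in cKO. Sums of FPKM were 452551.4 to 590620.8. Positions, transcript lengths and GC content came from GENCODE mouse release M21 (GRCm38), to which 23305 symbols matched directly and 674 through synonyms, 98.5% of the table; 361 did not match.

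Differences were tested in limma 3.58.1 (R 4.3.3) on log2(FPKM + 1) with genotype as the only term, an empirical Bayes variance prior with a trend on mean expression, and Benjamini-Hochberg adjustment over the 12172 genes with a mean of at least 0.5 FPKM over all 6 samples. All tests were two-sided, with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes near the floor; group means ± SD are of FPKM itself. The median log2 difference of all tested genes was 0.017. On simulated data for this comparison over 12172 genes, with 200 genes changed, the same fit called 68.2% of 4-fold, 33.3% of 2-fold and 1.5% of 1.5-fold changes, and 2 of its 70 calls were false. In the simulated lists the raised list was recovered and 0 of the others were called. The simulated noise was drawn independently for each gene, without the length and GC trends of the real libraries. The simulation therefore cannot show how often either test makes false calls where genes vary together.

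Gene lists (24 of pathways and processes, 8 of cell type markers) were fixed before the data were examined, as were the tests, the alternatives not described as added and the rule for naming genes. The 32 lists were tested with limma's camera at a preset correlation of 0.01 and at an estimated one, adjusted over all 32 lists. Each list's members were also adjusted over the list alone. Limma's fry, which asks whether a list's members differ without setting them against other genes, was planned for a shared direction. Its version for changes in either direction was not planned. Both were adjusted over all 32 lists. The rule names Hic1. It then takes the 12 genes with the largest rise and the 12 with the largest fall among those past adjusted p 0.05 whose groups do not overlap and whose mean reaches 1 FPKM in a group. For each list it takes up to 4 members past the threshold with the smallest adjusted p, or up to 2 with the highest mean where none passed. Predicted genes (Gm and Rik names) were passed over. Genes said to be outside the rule, and those in the other observations, were chosen after their values were seen.

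The alternatives were a pseudocount of 0.1, every gene above the floor tested, a mean of at least 2 FPKM, quantile normalization, median-ratio scaling, no variance trend, a robust prior, the replicate number as a block, a fold of at least 2, camera with an estimated correlation, and each library left out in turn. A correction for transcript length and GC content was added after the data were seen: each library's deviation from the mean of all libraries was regressed on natural splines (4 degrees of freedom) of both, and the fitted part was removed. Replicate numbers in the titles were not treated as pairs. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures with matplotlib 3.10.9.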

Results

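Messenger RNA was measured by strand-specific poly(A) sequencing in mesenchymal progenitors (MPs), the fibro-adipogenic stromal cells of skeletal muscle, purified by flow cytometric sorting from the hindlimb muscle of C57BL/6J mice aged 8 weeks. The 2 groups had 3 samples each. WT animals carried floxed Hic1 alleles and no Cre. In the conditional knockout (cKO) animals, a tamoxifen-inducible Cre driven by the ubiquitin C promoter acted on the same floxed alleles. The protocol, listed for all samples, gave tamoxifen at 2.5 mg per day for 5 days, followed by 10 days without it. The deposited table gives FPKM (fragments scaled to transcript length and library depth) for 24340 genes. Its low values move in steps of single fragments, which put the depth at an estimated 22000000, 20890000 and 17900000 fragments in WT replicates 1, 2 and 3. The same estimate was 27820000, 26320000 and 20380000 in cKO replicates 1, 2 and 3. Between 70.7% and 78.3% of the low values used lay within 0.1 step of a whole number. Pearson correlations between libraries, taken across genes on the log2 scale, ran from 0.957 to 0.985, and genes are not independent replicates. Within both groups the libraries also differed by transcript length. Across genes, Spearman's rho between a library's deviation from its group mean and transcript length was 0.61 in WT replicate 2 and 0.62 in cKO replicate 1, and −0.53 in both WT replicate 3 and cKO replicate 3. The labels do not say whether each library came from a separate animal, so p-values measure the spread between these 6 samples, which may be technical. Cre was present in the cKO group and absent from the WT group, so its presence and the deletion of Hic1 cannot be told apart here.

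Hic1, which encodes a zinc-finger transcriptional repressor and is the gene targeted by the deletion, was lower in each cKO library than in each WT library. Its FPKM values were 10.3, 16.7 and 5.49 in WT replicates 1 to 3, and 2.19, 1.04 and 0.504 in cKO replicates 1 to 3. The group means were 10.8 ± 5.64 FPKM in WT and 1.24 ± 0.862 in cKO (SD, n = 3 each), a ratio of 0.115. On the log2(FPKM + 1) scale, the difference was −2.35 ± 0.38 (SE), with a limma adjusted p of 0.0179. At the estimated depths, the cKO values stand for about 204, 91 and 34 fragments, against 760, 1169 and 329 in WT. Hic1 lies on chromosome 11 of GRCm38, from 75164565 to 75169519 on the minus strand. The labels do not state which exons are floxed, so the remaining signal in cKO could not be assigned to intact or deleted alleles. The call ended, at about the same log2 difference, without WT replicate 1 (limma adjusted p = 0.0962), without cKO replicate 2 (0.0953) and when every gene above the floor was tested (0.0869).

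The first question was which genes differed between MPs with and without the deletion. S100a4, which encodes a calcium-binding protein of the S100 family, rose from 322.6 ± 66.5 FPKM in WT to 3856 ± 1403 in cKO (SD, n = 3 each). H19, an imprinted long noncoding RNA, fell from 107.4 ± 41.0 to 9.97 ± 10.7 FPKM. In all, 279 of the 12172 genes tested passed an adjusted p of 0.05 in limma, 146 of them higher and 133 lower in cKO. Among them, 97 were at least 2-fold higher and 68 at least 2-fold lower on the log2(FPKM + 1) scale, and 24 and 7 were at least 4-fold higher and lower. The 3 WT and 3 cKO values did not overlap for any of the 279, whereas 16.5% of all tested genes and 10% by chance show no overlap. With 3 samples per group, this follows largely from the selection by p-value, so it is not separate support for the calls. At an unadjusted p under 0.05 there were 1437 genes. The count was 97 without WT replicate 1, 113 without cKO replicate 2 and 170 without WT replicate 3. It was 184 when every gene above the floor was tested, and 537 after a correction for transcript length and GC content.

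**Figure D1:**
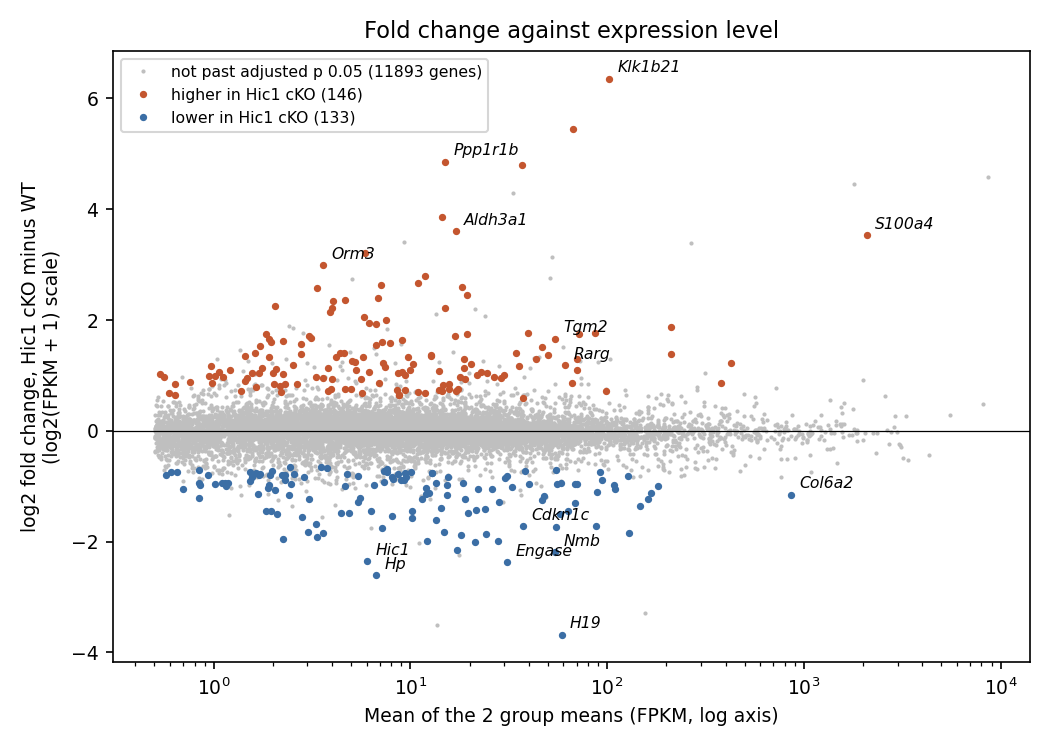
Log2 fold change (cKO minus WT, log2(FPKM + 1) scale) against the mean of both group means (FPKM, log axis) for the 12172 genes tested. Red points are the 146 genes higher in cKO and blue points the 133 lower past adjusted p 0.05. Grey points are the genes that did not pass.

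Among the 12 genes chosen for the largest rise, several had almost no signal in WT. Ppp1r1b, which encodes the phosphatase inhibitor DARPP-32, measured 0.0278 ± 0.0309 FPKM in WT and 29.9 ± 10.3 in cKO (SD, n = 3 each), with a log2 difference of 4.86 ± 0.21 (SE) and a limma adjusted p of 9.033e-05. Pik3r6, a regulatory subunit of phosphoinositide 3-kinase gamma, rose from 0.338 ± 0.144 to 11.4 ± 1.59 FPKM (limma adjusted p = 9.033e-05). Cib3, a calcium- and integrin-binding protein, rose from 1.05 ± 0.735 to 27.8 ± 4.25 FPKM, and Aldh3a1, an aldehyde dehydrogenase, from 1.81 ± 0.862 to 32.2 ± 1.56 FPKM. Orm3, an orosomucoid of the acute-phase plasma proteins, was listed at the table's lowest value of 0.01 in all 3 WT libraries and at 5.32, 7.198 and 8.98 FPKM in cKO. The transcription factors Foxo6 and Sox18 rose from 2.22 ± 0.602 to 19.7 ± 5.65 FPKM and from 1.26 ± 0.754 to 12.9 ± 3.83 FPKM. S100a4 had a log2 difference of 3.53 ± 0.30 (limma adjusted p = 0.000971). AA467197 rose from 2.42 ± 2.04 to 21.2 ± 7.47 FPKM (limma adjusted p = 0.01006), a call that ended without WT replicate 1 (0.0647), without cKO replicate 2 (0.0596) and with every gene above the floor tested (0.0622). Its difference of 2.79 became 3.25 without WT replicate 3.

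The remaining 3 of these 12 genes were tissue kallikreins, serine proteases encoded in one cluster on chromosome 7. Klk1b21 measured 0.740, 1.11 and 0.0761 FPKM in WT and 55.7, 79.9 and 475.5 in cKO replicates 1, 2 and 3 (limma adjusted p = 0.00318). Klk1b24 was at 26.3, 36.8 and 338.2 FPKM in cKO and at 0.626 ± 0.193 (SD, n = 3) in WT (limma adjusted p = 0.0111). Klk1b27 was at 7.30, 14.96 and 199.6 FPKM in cKO and at 0.0696 ± 0.103 in WT (limma adjusted p = 0.0468). Without cKO replicate 3, which held the highest value of each, the log2 differences went from 6.36 to 5.42 for Klk1b21, from 5.44 to 4.31 for Klk1b24 and from 4.81 to 3.43 for Klk1b27. Without cKO replicate 1 they became 6.96, 6.13 and 5.73 in the same order. The Klk1b24 call ended without WT replicate 1 or 3 (limma adjusted p of 0.0669 and 0.0572), with a robust prior (0.0705) and with every gene above the floor tested (0.0714). The Klk1b27 call ended without WT replicate 1, 2 or 3 (0.173, 0.0707 and 0.146), without cKO replicate 2 (0.114), with a robust prior (0.194) and with every gene above the floor tested (0.161). These genes resemble one another closely, so how fragments were shared out among them is uncertain.

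The 12 genes chosen for the largest fall included several secreted proteins. Haptoglobin (Hp) fell from 12.2 ± 3.77 FPKM in WT to 1.13 ± 0.191 in cKO (SD, n = 3 each), with a log2 difference of −2.60 ± 0.20 (SE) and a limma adjusted p of 0.000747. The neuropeptide gene Nmb (neuromedin B) fell from 90.2 ± 21.6 to 18.7 ± 3.10 FPKM, the cytokine gene Il17d from 45.0 ± 6.15 to 10.6 ± 1.42, and Pgf (placental growth factor) from 38.7 ± 11.7 to 9.79 ± 2.87. Engase, a cytosolic enzyme that trims N-glycans, fell from 52.7 ± 8.88 to 9.52 ± 2.56 FPKM. Lgi2 fell from 28.8 ± 4.88 to 5.71 ± 1.23 FPKM, Cpxm2 from 34.7 ± 3.70 to 8.14 ± 2.55, Susd2 from 29.0 ± 3.65 to 7.24 ± 1.97, and Stmn2, a microtubule regulator of the stathmin family, from 4.21 ± 1.56 to 0.302 ± 0.0479. The imprinted gene Mest fell from 20.0 ± 5.97 to 4.35 ± 1.76 FPKM (limma adjusted p = 0.0102), and the transcriptional coregulator Cited1 from 5.93 ± 3.64 to 0.749 ± 0.518 (limma adjusted p = 0.0286). The H19 difference was −3.68 ± 0.58 (limma adjusted p = 0.0155), and −4.44 without cKO replicate 3, where H19 stood at 22.3 FPKM against 4.21 and 3.39 in cKO replicates 1 and 2. The H19 call ended without WT replicate 1 or 3 or cKO replicate 2 (0.0848, 0.0577 and 0.0667), the Mest call without WT replicate 1 (0.0680), and the Cited1 call without WT replicate 1 or 3 or cKO replicate 1 or 2 (0.0581, 0.0605, 0.0723 and 0.136). With every gene above the floor tested, the adjusted p was 0.0811 for H19, 0.0599 for Mest and 0.116 for Cited1.

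**Figure D2:**
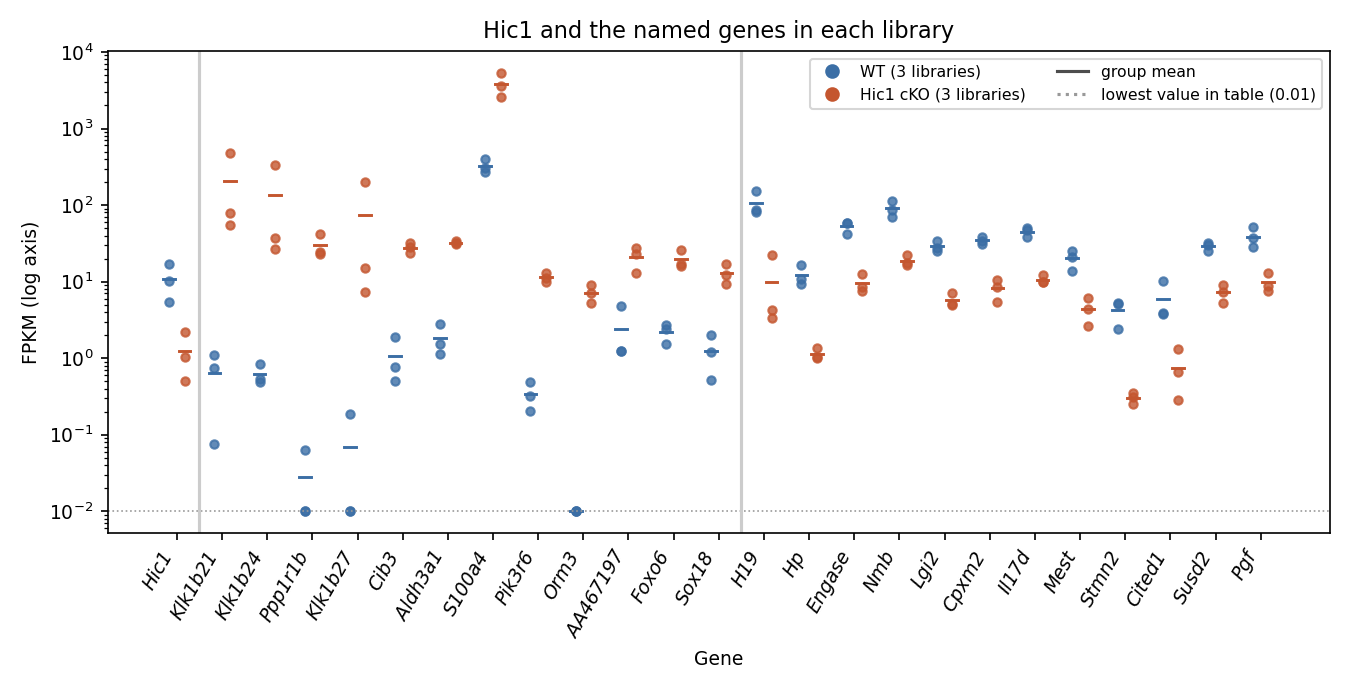
FPKM (log axis) in each of the 3 WT and 3 cKO libraries for Hic1, the 12 genes chosen for the largest rise and the 12 chosen for the largest fall; short bars are group means. The groups do not overlap for any of these genes, and the 3 kallikrein genes are highest in cKO replicate 3.

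The 32 lists of genes fixed before the data were examined asked whether matrix, lineage, signalling and cell cycle genes moved together. With the preset correlation of 0.01 between genes, 3 lists passed an adjusted p of 0.05 in limma's camera, each of them lower in cKO. With an estimated correlation 0 lists passed, 1 list had an unadjusted p under 0.05 (the retinoic acid list, 0.0425), and adjusted p-values ran from 0.868 to 0.998. The preset correlation also called 4 to 13 lists in each of the 9 other ways to divide the 6 libraries 3 against 3. The number of lists called therefore does not set the genotype apart. Each of those splits had WT and cKO libraries on both sides, and which lists they called was not recorded. They cannot decide about any single list. The basement membrane and fibrillar collagen lists passed at the preset correlation in all 15 other settings. At the preset correlation, 10 lists that did not pass did so in another setting. Leaving out cKO replicate 3 brought the camera adjusted p to 0.0180 for the adipogenic list, 0.00829 for tenocyte genes, 0.00418 for tenocyte markers, 0.00633 for interferon-stimulated genes and 0.00829 for Schwann cell markers. Without WT replicate 3 it was 0.00208 for tenocyte genes, 0.000736 for tenocyte markers and 0.0443 for the Wnt list. Without cKO replicate 1 it was 0.000867 for the Wnt list and 0.000324 for the Hedgehog list. Without WT replicate 1 or cKO replicate 2 it was 0.0395 and 0.0277 for haematopoietic markers. The retinoic acid list passed without any 1 library except WT replicate 2 (0.0206 to 0.0435), with the replicate block (0.0256) and with median-ratio scaling (0.0470). With the replicate block, the camera adjusted p was also 0.0393 for haematopoietic markers, 0.0480 for tenocyte markers and 0.0479 for Schwann cell markers. The Wnt list passed with every gene above the floor tested (0.0267), and Schwann cell markers with a mean of at least 2 FPKM required (0.0116). The mitosis list is given with the cell cycle genes. In limma's fry for a shared direction, the lowest adjusted p was 0.117, for the retinoic acid list. For changes in either direction, the fry adjusted p was 4.82e-05 for HIC1 targets and for endothelial genes, and 0.000293 for complement genes. It was 0.00350 for basement membrane genes, 0.0726 for the fibrillar collagen list and 0.502 for muscle fibre genes.

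Basement membrane genes were the list with the lowest median. Of the 14 measured members, 3 fell and 0 rose over all genes tested, and 8 fell when adjusted over the list alone. Col15a1 fell from 209.7 ± 37.8 FPKM in WT to 82.8 ± 21.8 in cKO (SD, n = 3 each), Col18a1 from 44.1 ± 0.596 to 21.3 ± 2.25, and the laminin gene Lama4 from 114.7 ± 8.10 to 68.3 ± 3.73. The list's median log2 difference was −0.52, with 12 of 14 members below 0 (camera adjusted p = 7.495e-08, and adjusted p = 0.868 with an estimated correlation). Of the 30 fibrillar collagen and matrix assembly genes, 1 fell, and 4 fell when adjusted over the list alone (Col5a1, Col5a3, Col6a1 and Col6a2). Col6a2, a chain of type VI collagen, went from 1185 ± 90.7 to 538.4 ± 96.0 FPKM (limma adjusted p = 0.0286). The median of that list was −0.28, with 25 of 30 members below 0 (camera adjusted p = 0.000208, and adjusted p = 0.998 with an estimated correlation). Tenocyte markers, 1 of which (Fmod) is also in that list, lay lower too, with a median of −0.50 and 6 of 7 below 0. Their camera adjusted p was 0.0840, and 0.998 with an estimated correlation. Of the 7 markers, 0 had an unadjusted p under 0.05 in limma, and Thbs4 was at 277.0 ± 75.3 FPKM in WT and 279.6 ± 82.8 in cKO. With 1 library left out, both lists had their lowest camera adjusted p without WT replicate 3 (2.54e-09 and 0.000736) and their highest without WT replicate 2 (0.0262 and 0.622). Whether fewer tenocytes in the sorted cells lie behind both was not tested. Matrix remodelling enzymes and inhibitors had 0 of 20 members past the test in limma, with 2 at an unadjusted p under 0.05 and a camera adjusted p of 0.664; Timp2 was at 1069 ± 12.3 and 1205 ± 52.8 FPKM and Mmp2 at 695.6 ± 53.1 and 760.6 ± 100.5. The muscle fibre list was also lower at the preset correlation (camera adjusted p = 0.0143, and adjusted p = 0.998 with an estimated correlation), with 0 of its 12 members past the test in limma. Col18a1 stayed past the threshold in all 15 other settings. The Col15a1 call (limma adjusted p = 0.0216) ended without WT replicate 1 (0.124), without cKO replicate 2 (0.0913) and with every gene above the floor tested (0.0747). The Col6a2 call ended without any 1 library except cKO replicate 3: the values were 0.173, 0.0571 and 0.0667 without WT replicates 1, 2 and 3, and 0.0696 and 0.182 without cKO replicates 1 and 2. It also ended with every gene above the floor tested (0.0832) and with the replicate number as a block (0.0629). The Lama4 call (limma adjusted p = 0.0247) ended without WT replicates 1 and 2 (0.152 and 0.0598), without cKO replicates 1, 2 and 3 (0.0540, 0.169 and 0.0755), with quantile normalization (0.0553) and with the replicate block (0.0548).

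Of 19 measured markers of MPs themselves, Hic1 and Col15a1 fell and 0 rose over all genes tested, 8 had an unadjusted p under 0.05, and 3 fell when adjusted over the list alone (Thy1 was the third). Hic1 is the deleted gene, so its fall was set by the design, and these counts and the list's camera test include it. Named outside the rule because they define the cells, Pdgfra was at 120.6 ± 39.1 FPKM in WT and 117.7 ± 15.9 in cKO (SD, n = 3 each) and Ly6a (Sca-1) at 1777 ± 349.2 and 1805 ± 287. The camera adjusted p of the list was 0.0874. Of 18 adipogenic genes, 1 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.266). Plin4, a lipid droplet coat protein, rose from 0.963 ± 0.298 to 5.31 ± 1.14 FPKM, and lipoprotein lipase (Lpl) fell from 242.2 ± 18.2 to 121.9 ± 24.0 FPKM. Of 13 osteogenic and chondrogenic genes, 0 passed in limma, 5 had an unadjusted p under 0.05, and 2 were higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.997). Bmp1 was at 284.1 ± 16.9 and 294.4 ± 17.5 FPKM and Comp at 52.0 ± 2.55 and 77.8 ± 8.26, the latter with a limma adjusted p of 0.0798 that became 0.0230 after the length and GC correction. Of 11 tenocyte genes, 0 passed in limma, 2 had an unadjusted p under 0.05 and 1 was higher when adjusted over the list alone (camera adjusted p = 0.109); Egr1 was at 889.5 ± 42.3 and 970.9 ± 262.4 FPKM. The Col15a1 call ended without WT replicate 1 (0.124) or cKO replicate 2 (0.0913), and the Hic1 call without the same 2 libraries (0.0962 and 0.0953). With every gene above the floor tested, the adjusted p was 0.0747 for Col15a1 and 0.0869 for Hic1. The Lpl call (limma adjusted p = 0.0247) ended without WT replicate 1 or 3 (0.153 and 0.0667), without cKO replicate 1 or 2 (0.0654 and 0.145) and with every gene above the floor tested (0.0602).

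Genes of retinoic acid metabolism and response moved in both directions. Of 17 measured members, 4 rose and 1 fell, and 8 rose and 3 fell when adjusted over the list alone. The receptor gene Rarg rose from 36.8 ± 4.08 FPKM in WT to 85.4 ± 10.1 in cKO (SD, n = 3 each), with a log2 difference of 1.19 ± 0.15 (SE) and a limma adjusted p of 0.00508. Cyp26b1, which degrades retinoic acid, rose from 4.03 ± 1.84 to 14.1 ± 1.78 FPKM, and Crabp1, which binds it in the cytosol, from 1.76 ± 0.466 to 10.6 ± 6.21. Rbp4, the plasma carrier of retinol, fell from 40.7 ± 10.1 to 15.8 ± 1.61 FPKM (limma adjusted p = 0.0102). The fourth gene that rose, Stra6, a membrane receptor for Rbp4 named here outside the rule, went from 0.405 ± 0.225 to 2.02 ± 0.564 FPKM (limma adjusted p = 0.0209). The median log2 difference of the list was 0.29 (camera adjusted p = 0.0511, and adjusted p = 0.868 with an estimated correlation). At the preset correlation, the camera adjusted p was 0.0256 with the replicate block and 0.0470 with median-ratio scaling. Without WT replicate 1, the limma adjusted p was 0.0769 for Cyp26b1, 0.0715 for Crabp1, 0.0648 for Rbp4 and 0.110 for Stra6. Without cKO replicate 2 it was 0.0707 for Cyp26b1, 0.0667 for Rbp4 and 0.0953 for Stra6, and without WT replicate 3 it was 0.0831 for Crabp1. With every gene above the floor tested, it was 0.0666 for Cyp26b1, 0.0909 for Crabp1 and 0.0558 for Stra6.

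Other signalling lists had at most 1 member past the test. Of 30 TGF-beta and BMP genes, follistatin (Fst), a secreted antagonist of activins, fell from 84.9 ± 6.43 FPKM in WT to 24.9 ± 3.01 in cKO (SD, n = 3 each; log2 difference −1.73 ± 0.14, limma adjusted p = 0.000769). When adjusted over the list alone, 4 of these genes were higher and 2 lower (camera adjusted p = 0.824). Of 23 Wnt pathway genes, the secreted inhibitor Sfrp1 fell from 32.0 ± 7.25 to 11.3 ± 2.76 FPKM, with 2 genes higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.0874). The Sfrp1 call (limma adjusted p = 0.0122) ended without WT replicate 1 (0.0680), without cKO replicate 2 (0.0618) and with every gene above the floor tested (0.0563). Of 11 Hedgehog pathway genes, 0 passed in limma and 0 when adjusted over the list alone, with 3 at an unadjusted p under 0.05 (camera adjusted p = 0.165). Gas1 was at 146.8 ± 16.7 and 95.5 ± 16.0 FPKM and Cdon at 26.6 ± 7.29 and 34.1 ± 5.68.

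A further question was whether genes of quiescence and of the cell cycle differed between the groups. Among 19 quiescence genes and negative regulators of the cell cycle, the cyclin-dependent kinase inhibitor gene Cdkn1c fell from 58.0 ± 11.8 FPKM in WT to 16.9 ± 3.98 in cKO (SD, n = 3 each), with a log2 difference of −1.72 ± 0.21 (SE) and a limma adjusted p of 0.00508. Its relative Cdkn1a rose from 29.8 ± 1.13 to 45.4 ± 3.40 FPKM (limma adjusted p = 0.0478). Adjusted over the list alone, 1 gene of that list rose and 2 fell, and its camera adjusted p was 0.824. Of 21 genes of S phase and replication, 0 passed in limma and 0 when adjusted over the list alone, with 1 at an unadjusted p under 0.05 (camera adjusted p = 0.997); Pcna was at 36.1 ± 1.57 and 38.2 ± 3.89 FPKM and Mcm6 at 11.2 ± 1.92 and 12.5 ± 0.8498. Of 20 genes of G2/M and mitosis, 0 passed in limma, 0 when adjusted over the list alone and 0 at an unadjusted p under 0.05, although all 20 had log2 differences above 0, with a median of 0.20. The camera adjusted p of the mitosis list was 0.0874, and 0.998 with an estimated correlation. At the preset correlation it became 6.489e-08 without cKO replicate 2, 0.000525 without WT replicate 1, 0.833 without WT replicate 3 and 0.0480 with the replicate block. Ube2c was at 6.62 ± 2.41 and 7.51 ± 4.21 FPKM and Cdc20 at 4.38 ± 2.45 and 5.23 ± 2.25. Of 20 p53 targets, Cdkn1a alone rose, also when adjusted over the list alone (camera adjusted p = 0.944). Of 12 genes reported elsewhere as HIC1 targets, 2 rose and 1 fell, with 2 and 2 when adjusted over the list alone (camera adjusted p = 0.997). They were Cdkn1a, Cdkn1c and Tgm2, a transglutaminase, which rose from 24.6 ± 0.946 to 84.4 ± 34.0 FPKM (limma adjusted p = 0.0111). The Tgm2 call ended without WT replicate 1 (0.0698) and with every gene above the floor tested (0.0558). The Cdkn1a call ended without any 1 of the 6 libraries. Its adjusted p was 0.238, 0.0708 and 0.114 without WT replicates 1, 2 and 3, and 0.0725, 0.208 and 0.148 without cKO replicates 1, 2 and 3. It also ended with a mean of at least 2 FPKM required (0.0554), without a variance trend (0.0554), with a robust prior (0.0548) and with the replicate block (0.0889).

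Among 21 cytokines and chemokines, Cxcl12 rose from 268.7 ± 23.6 FPKM in WT to 493.3 ± 62.5 in cKO (SD, n = 3 each), and 7 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.459). The Cxcl12 call (limma adjusted p = 0.0418) ended without any 1 of the 6 libraries. Its adjusted p was 0.238, 0.0520 and 0.119 without WT replicates 1, 2 and 3, and 0.0788, 0.139 and 0.116 without cKO replicates 1, 2 and 3. It also ended with quantile normalization (0.0530), with the replicate block (0.0852) and with every gene above the floor tested (0.0721). Among 21 glycolysis and hypoxia genes, the monocarboxylate transporter gene Slc16a3 rose from 0.712 ± 0.140 to 2.79 ± 0.540 FPKM (limma adjusted p = 0.00842), also when adjusted over the list alone (camera adjusted p = 0.824). Of 6 further lists, 0 members passed in limma, over all genes tested or adjusted over the list alone. The 25 interferon-stimulated genes (3 at an unadjusted p under 0.05) had a camera adjusted p of 0.0874, with Ifi27 at 246.4 ± 61.9 and 235.3 ± 32.4 FPKM. The 15 complement genes (2 at an unadjusted p under 0.05) had a camera adjusted p of 0.939, with C3 at 1102 ± 184.9 and 984.2 ± 172.3 FPKM. The 22 immediate early and dissociation stress genes (1 at an unadjusted p under 0.05) had a camera adjusted p of 0.664, with Fos at 1060 ± 89.8 and 1042 ± 261.7 FPKM. The 23 genes of oxidative phosphorylation and the 24 cytosolic ribosomal protein genes had 0 members at an unadjusted p under 0.05, with camera adjusted p-values of 0.939 and 0.997. The 19 cholesterol synthesis genes had 1 such member and a camera adjusted p of 0.939. The median, the mean and the direction of the camera test differed in sign for 9 lists, none of which passed camera. These were quiescence, HIC1 targets, osteogenic, TGF-beta and BMP, complement, glycolysis, ribosomal, satellite cell and endothelial.

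Transcripts of other cells of muscle asked whether the sorted populations differed in makeup. Muscle fibre genes were lower in cKO as a list: 0 of 12 members passed in limma or adjusted over the list alone, 2 had an unadjusted p under 0.05, and 11 of 12 lay below 0 with a median of −0.33. The camera adjusted p was 0.0143, and adjusted p = 0.998 with an estimated correlation. With the preset correlation, that call ended without WT replicate 1 or 3 (0.128 and 0.0710) or cKO replicate 1 (0.132). Tpm2 was at 16.4 ± 4.502 FPKM in WT and 9.24 ± 3.68 in cKO (SD, n = 3 each) and Tnnt3 at 10.1 ± 2.64 and 8.82 ± 1.88. Among 11 endothelial genes Sox18 alone rose, also when adjusted over the list alone (camera adjusted p = 0.997), while Pecam1 was at 1.97 ± 0.410 and 2.61 ± 0.539 FPKM and Cdh5 at 2.31 ± 0.199 and 1.44 ± 0.362, both named outside the rule. Among 11 pericyte and smooth muscle genes, smooth muscle actin (Acta2) rose from 12.7 ± 2.57 to 25.2 ± 4.15 FPKM, also when adjusted over the list alone (camera adjusted p = 0.664). The Acta2 call (limma adjusted p = 0.0329) ended without any 1 of the 6 libraries. Its adjusted p was 0.0603, 0.0603 and 0.0956 without WT replicates 1, 2 and 3, and 0.0683, 0.0991 and 0.0954 without cKO replicates 1, 2 and 3. It was 0.0880 with every gene above the floor tested. Of 9 haematopoietic genes, 0 passed in limma, 3 had an unadjusted p under 0.05 and 1 was higher when adjusted over the list alone. Of the 9, 7 lay above 0 with a median of 0.29 (camera adjusted p = 0.0874, and 0.0393 with the replicate block). Lyz2 was at 2.24 ± 1.17 and 6.70 ± 2.68 FPKM, with a limma adjusted p of 0.0861 that became 0.00371 with the replicate block. Of 3 measured satellite cell and myoblast genes, 0 passed in limma, 2 had an unadjusted p under 0.05 and 1 was lower when adjusted over the list alone (camera adjusted p = 0.997); Des was at 13.3 ± 5.09 and 21.4 ± 6.63 FPKM. The erythroid (5 genes), Schwann cell and glia (7) and tenocyte marker (7) lists had 0 members past limma's test, over all genes or adjusted over the list alone. They had 0, 2 and 0 members at an unadjusted p under 0.05, and camera adjusted p-values of 0.824, 0.0840 and 0.0840. Schwann cell and glia markers lay lower in cKO, with 5 of 7 below 0 and a median of −0.27, and tenocyte markers too, with 6 of 7 below 0 and a median of −0.50. Pmp22 was at 419.6 ± 26.7 and 296.9 ± 22.4 FPKM, Thbs4 at 277.0 ± 75.3 and 279.6 ± 82.8, and Hba-a1 at 39.0 ± 26.0 and 43.8 ± 39.0.

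**Figure D3:**
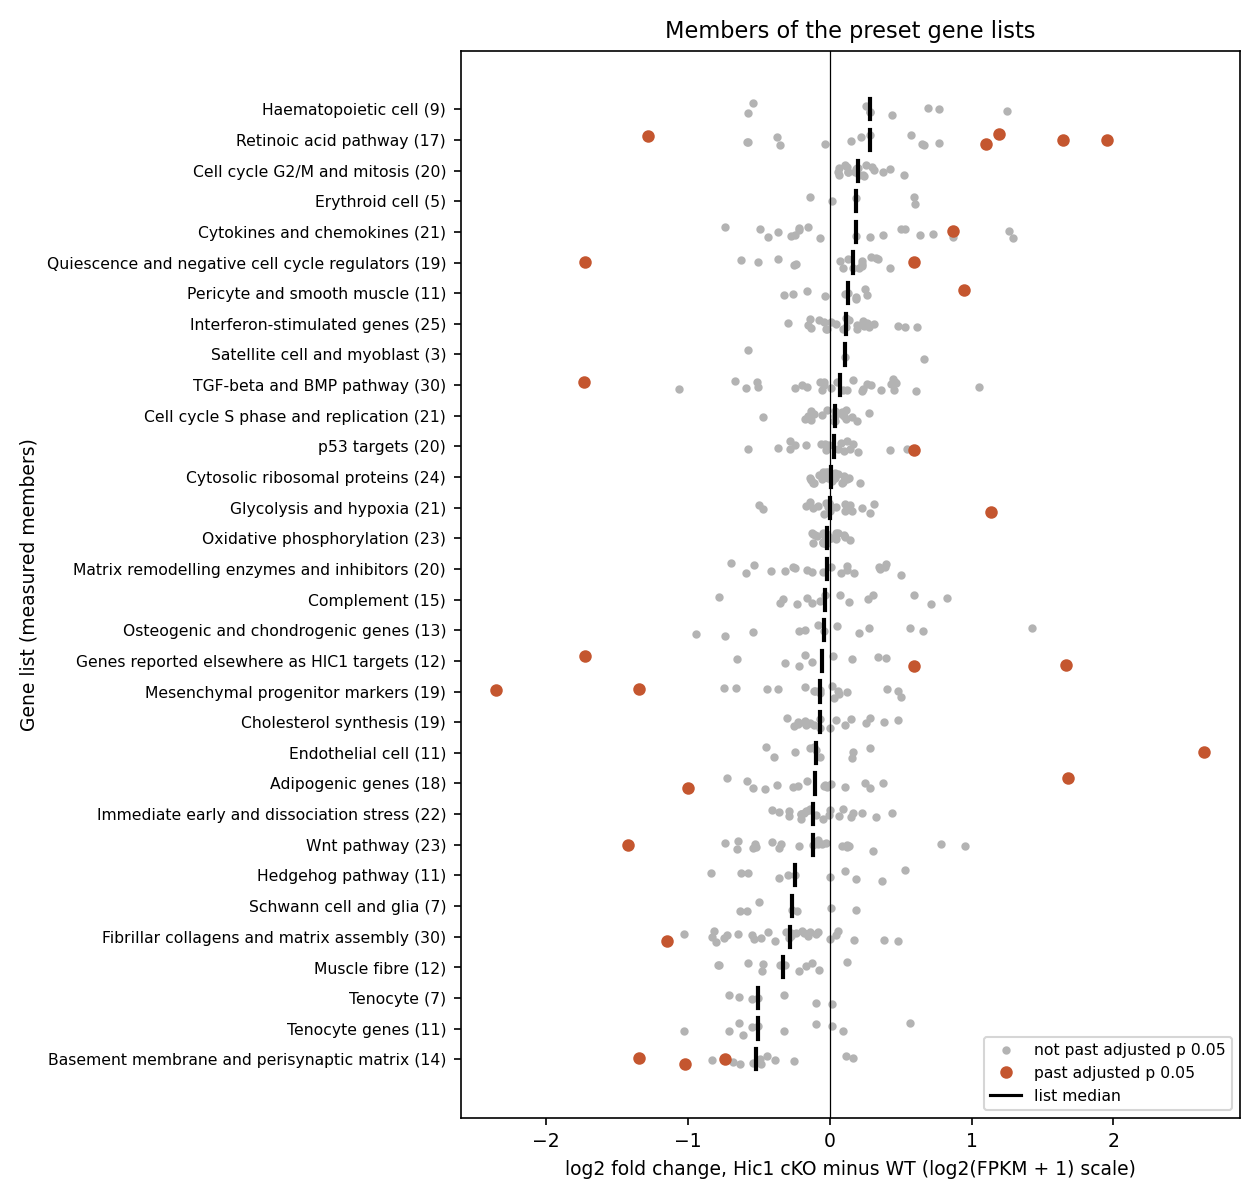
Log2 fold change (cKO minus WT, log2(FPKM + 1) scale) of each measured member of the 32 lists, ordered by the list's median (black bar). Red points passed adjusted p 0.05 over all genes tested; basement membrane genes have the lowest median, −0.52, and 12 of 14 members below 0.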

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

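The length and GC correction and the tests on it were chosen after the results were seen; the others were planned. None of the 279 called genes changed sign in any of the 15 other fits that tested it. For most of these fits this was fixed in advance, because the WT and cKO values do not overlap for any of the 279. Only quantile normalization, median-ratio scaling and the length and GC correction could have changed a sign. Between 184 and 537 genes passed in the 9 that kept all 6 libraries. Testing every gene above the floor gave 184 genes (97 higher, 87 lower) and kept 148 of the 279. It left Hic1 at −2.35 with a limma adjusted p of 0.0869 (range over the other settings 0.00149 to 0.0962); the cause was not tested. The length and GC correction gave 537 genes (276 higher, 261 lower) and kept 270 of the 279. A fold of at least 2 gave 165 genes (97 higher, 68 lower), fewer by construction. With 1 library left out, 97 to 295 genes passed, 65 to 142 higher and 32 to 153 lower, and 3 to 9 lists; Hic1 ran from −2.73 to −2.00. The fewest came without WT replicate 1 (97 genes) and without cKO replicate 2 (113), and the share that was higher went from 52.3% to 67.0% and 63.7%. Fewer samples entered these fits, and a lower count does not mean that the library left out drives the calls. WT replicate 1 and cKO replicate 2 had the rho with transcript length nearest 0 in their groups (−0.189 and −0.257). The libraries kept in those groups had opposite signs: 0.610 and −0.528 in WT, 0.623 and −0.526 in cKO. Whether that spread lowered the counts was not tested. Camera with an estimated correlation called 0 lists against 3 with the preset one.

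The replicate numbers showed no clear pairing of the libraries. The deviations of same-numbered libraries correlated at −0.20, −0.23 and 0.29, and WT replicate 2 correlated most with cKO replicate 1 (0.57). These correlations also carry the length differences between libraries, so they cannot exclude a shared batch. With the replicate number as a block, 309 genes passed (156 higher, 153 lower), 239 of the 279 were kept, and 8 lists passed; the cause was not tested. Of the 43 genes named by the rule that passed, 24 did so in every setting, 1 was lost only when a library was left out, and 18 were lost in some other setting too. Of the 35 that did not pass, 2 gained a call (Comp, Lyz2). Uncalled genes near 0 can differ in sign between fits. The authors' own statistics and a count test were not run, as the table used here holds FPKM alone. Depth limits genes near the floor: 1 fragment sets whether a WT value is 0.01 or above.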

Other observations

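The gene groups and tests of Smg6 below were chosen after the called genes were seen. The length and GC correction was also added after the main results were seen. What the tests of that correction, of the splits and of the imprinted list would show under each explanation was set out before their own results. A list of 39 genes of the neuronal cytoskeleton and secretory granules, expressed at low to moderate levels in these cells, had 20 measured members. Of these, 8 fell and 0 rose over all genes tested, and 13 fell when adjusted over the list alone. Besides Stmn2, the growth cone gene Gap43 fell from 16.4 ± 2.73 FPKM in WT to 6.38 ± 0.763 in cKO (SD, n = 3 each; limma adjusted p = 0.00569), the actin-bundling gene Fscn1 from 29.2 ± 1.99 to 10.2 ± 3.77, the granule protein gene Scg3 from 24.6 ± 2.42 to 12.3 ± 1.03, and the secreted pentraxin gene Nptx2 from 3.35 ± 0.554 to 0.587 ± 0.109. Stmn3, Tubb3 and Tubb2b also fell. The list's median log2 difference was −0.59 (camera adjusted p = 7.83e-14, and adjusted p = 0.0206 with an estimated correlation, over the 3 lists added this way). Since it was drawn up from called genes, its test is not independent evidence. Schwann cell and glia markers, none of them in this list, also lay lower: their median was −0.27, with 5 of 7 below 0 (camera adjusted p = 0.0840, 0.0479 with the replicate block, 0.00829 without cKO replicate 3, and adjusted p = 0.998 with an estimated correlation). A smaller share of nerve-associated cells was not tested and stays open. Without WT replicate 1 the limma adjusted p was 0.0768 for Fscn1, 0.0669 for Scg3, 0.0885 for Stmn3, 0.128 for Tubb3 and 0.212 for Tubb2b. Without cKO replicate 2 it was 0.0839 for Stmn3, 0.117 for Tubb3 and 0.198 for Tubb2b. Without WT replicate 3 it was 0.0547 for Stmn3, 0.0831 for Tubb3 and 0.115 for Tubb2b; without cKO replicate 3 it was 0.0886 for Tubb3 and 0.118 for Tubb2b; and without WT replicate 2 it was 0.0613 for Tubb3. With every gene above the floor tested, it was 0.0558 for Fscn1, 0.0708 for Stmn3, 0.101 for Tubb3 and 0.0894 for Tubb2b, and after the length and GC correction it was 0.0725 for Tubb3.

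Some members of gene families rose; the other members were not counted. Of the secreted phospholipase genes on chromosome 4, Pla2g2e rose from 4.62 ± 1.33 FPKM in WT to 25.4 ± 6.83 in cKO (SD, n = 3 each; limma adjusted p = 0.00205), Pla2g5 from 0.781 ± 0.200 to 6.99 ± 1.81 and Pla2g2d from 0.355 ± 0.112 to 2.55 ± 0.980. The acetyltransferase family genes Nat8, Cml1 and Cml5 on chromosome 6 rose from 0.799 ± 0.144 to 8.52 ± 2.66, from 2.36 ± 0.314 to 12.7 ± 3.00 and from 0.845 ± 0.305 to 4.71 ± 2.04 FPKM. Apol9a and Apol9b on chromosome 15 rose from 2.89 ± 0.340 to 10.6 ± 2.85 and from 1.605 ± 0.139 to 9.96 ± 1.64 FPKM. The families share sequence, so the split among members is uncertain. Single genes that rose, with no list behind them, included the transporters Slc6a4 (serotonin) from 0.792 ± 0.381 to 7.22 ± 0.787 FPKM and Slc6a2 (noradrenaline) from 5.07 ± 0.256 to 14.4 ± 0.487, and the oxidase Maob from 18.3 ± 1.08 to 50.4 ± 5.16. Of 9 measured kallikrein genes, 3 rose, and 7 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 2.716e-07, and adjusted p = 0.104 with an estimated correlation). The kallikrein list was chosen after the called genes were seen, so its counts and its test are not independent evidence. The Pla2g2d call (limma adjusted p = 0.0151) ended without WT replicate 1 or 3 (0.0648 and 0.0587) or cKO replicate 2 (0.0550), and the Cml5 call (0.0217) without the same libraries (0.122, 0.0563 and 0.114). Both also ended with every gene above the floor tested (0.0553 for Pla2g2d and 0.0900 for Cml5).

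Smg6, which encodes a nuclease of nonsense-mediated decay, lies beside Hic1 on the opposite strand (chromosome 11, 74925823 to 75164448), with 117 nt between the 3′ ends of the 2 genes. It rose from 8.34 ± 0.248 to 30.3 ± 0.976 FPKM (SD, n = 3 each; log2 difference 1.74 ± 0.11, limma adjusted p = 0.000273). Fragments lost from Hic1 and counted to Smg6 would be too few for the rise. Smg6 gained 3.82 times the depth-scaled fragments that Hic1 lost, as estimated from FPKM. Its smallest gain in a library was 2.06 times the highest Hic1 level in any library. The comparison cannot exclude transcripts of the Hic1 locus in cKO that exceed the measured Hic1 level and were counted to Smg6. The genes around Hic1 did not rise as a group. The 24 other tested genes within 500 kb had a median log2 difference of 0.03, with an upper 95% bootstrap bound of 0.203. Of these, 1 was called (Slc43a2, 362.2 kb away, from 1.95 ± 0.464 to 6.78 ± 1.01 FPKM). Rtn4rl1, which starts at 75193783, had a log2 difference of 0.802 ± 0.209 (SE) without being called (limma adjusted p = 0.108). Ovca2 and Dph1, which lie between it and Hic1, were at 0.066 and 0.219. A median over this window cannot exclude an effect limited to the nearest genes. Whether the rise of 1.744 follows a loss of HIC1 protein or of DNA near Smg6 cannot be told apart. Both would come with the deletion in each cKO library. Protein was not measured, and the labels do not state which exons are floxed. Transcripts that run past the deleted part of Hic1 were not tested.

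The libraries differed by transcript length and GC content within both groups, so a length or GC bias could add to or hide calls. For GC content, Spearman's rho with a library's deviation from its group mean ran from −0.406 in WT replicate 2 to 0.417 in WT replicate 3. The groups differed too: across genes, rho of the log2 difference (cKO minus WT) was 0.165 with transcript length and −0.292 with GC content. It does not account for the 279 calls as a whole: after the correction, 270 of them kept their direction and their side of the threshold, and 537 genes passed. The other 9 ways to divide the libraries called at most 1 gene against 279, but 10 splits cannot give a share under 0.05 (1 of 10 was as large as the real one, itself). For lists at the preset correlation the real split gave 3 and the others up to 13, so all 10 splits gave at least as many; 10 are again too few for a share under 0.05, and with an estimated correlation every split, the real one included, called 0 lists. The many calls of the other splits could come from a structure of the libraries or from a preset correlation that is too low, which was not tested. Differences in genotype besides Hic1, such as the Cre transgene, remain open and untested.

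Some imprinted genes with roles in fetal growth fell. Of 34 measured members of a list of imprinted genes, 4 fell and 0 rose, and 6 fell when adjusted over the list alone. Besides H19, Mest and Cdkn1c, these 4 included Igf2, from 7.64 ± 1.32 FPKM in WT to 2.09 ± 0.480 in cKO (SD, n = 3 each; limma adjusted p = 0.00411). After the length and GC correction 4 of the 4 stayed lower past the threshold, so such a bias is not the whole cause. Whether imprinted genes move as a set stays open, as the camera adjusted p was 0.000533 with the preset correlation and 0.1039 with an estimated one, and most of the 34 did not pass. The list's median log2 difference was −0.106, with 11 members above 0 and 23 below. Since the list was chosen after the called genes were seen, its test is not independent evidence. Without WT replicate 1 the limma adjusted p was 0.0848 for H19 and 0.0680 for Mest, and H19 also lost its call without WT replicate 3 (0.0577) and cKO replicate 2 (0.0667). With every gene above the floor tested, it was 0.0811 for H19 and 0.0599 for Mest. A link to the loss of HIC1 was not tested and remains open beside other effects of the Cre.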
